A study of Mus musculus with 10 samples.

How the data were processed

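Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed for 10 samples of mouse cells, 6 ChIP libraries and 4 input libraries. The cells were the CGR8 embryonic stem cell (ESC) line, grown without feeders in serum with LIF, and endoderm derived from it. Per the labels, endoderm was obtained with 100 ng/ml Activin A, a TGF-beta family ligand that acts through SMAD2 and SMAD3, added from day 2, and chromatin was taken at day 4. SB431542 (SB), an inhibitor of the TGF-beta, activin and Nodal type I receptor kinases, was used at 10 µM for 24 hours in ESCs and for 48 hours in the differentiating cells, as read from the labels, whose wording on its timing relative to Activin A leaves room for another reading. The antibodies were against SMAD2/3 and against HEB, the E protein encoded by Tcf12. SMAD2/3 was profiled without SB only. Each group held 1 ChIP library, so no replicate spread was measurable, no test across samples was made and no p-value was computed.

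Sequencing was on the Genome Analyzer II per the labels, and the submitters' processing notes name CASAVA 1.8.2 and genome build mm9. The aligner, the peak caller with its settings and the gene annotation are not given in the sources used here. The authors deposited 1 list of enriched regions per ChIP library. Per the labels, nothing states that libraries were pooled. Input libraries entered only through the background columns of the lists and their own reads were not analysed here.

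Per the file headers, each region carries its position, the count of ChIP tags and of background tags in it, and both are whole numbers in the deposited lists. The authors' ratio of tags, here called tag enrichment, was the quotient of these counts in 83.7% (Endoderm HEB) to 97.9% (ESC+SB HEB) of regions, and in the other regions the background count was replaced by a floor proportional to region width, at 17.6 to 20.0 tags per kb. The ratio was not scaled for sequencing depth as far as the values show. The deposited signal of a region is the height of its ChIP peak and of the background at the same position, with no stated scaling, and the smallest ChIP height was 25.0 in 5 lists and 28.0 in the ESC+SB HEB list. The authors' column headed −log10 q-value started at 98.8 in the Endoderm HEB list and no lower in any other, values too large for its named scale, so it was not used. Whether coordinates count from 0 or 1 is not given in the sources used here, and they are printed as deposited. Identical background counts were found in 87% of 100 ESC SMAD2/3 and ESC HEB region pairs whose edges lay within 10 bp, and in 81.4% of 177 such Endoderm SMAD2/3 and Endoderm HEB pairs. The shares were 4.95% of 606 pairs between ESC HEB and ESC+SB HEB and 8.57% of 105 pairs between Endoderm HEB and Endoderm+SB HEB. SMAD2/3 and HEB lists of the same cells were therefore treated as sharing an input.

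A region listed for several genes was counted once. Gene assignment was the authors', who list a gene when the region lies in it or within 1 kb of it. A gene was counted for a list only by this assignment, so a gene counted for 1 list alone can have a region that overlaps an unassigned region of the other. Regions within 1 kb of the listed gene's 5′ end are called promoter-proximal. Exons, introns and untranslated regions were not annotated, since the reference used here was a GRCm38.p6 table of gene names without mm9 positions. That table served only for names: 10640 of 10730 listed symbols (99.2%) matched a symbol or a single synonym.

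Region lists were compared by overlap of at least 1 bp. Shares have exact Clopper-Pearson 95% confidence intervals, which cover counting error only and not the spread between cultures or libraries. A chance level came from 1000 circular rotations of the second list within each chromosome (seed 1). The rotations do not keep regions at promoters or open chromatin, so lists of regulatory regions can exceed them without joint binding. HEB regions overlapping a SMAD2/3 region of the same cells are called co-bound, and the share of them also listed with SB was compared with that of the other HEB regions, as listed and standardized over quintiles of tag enrichment. Endoderm SMAD2/3 regions without an ESC SMAD2/3 region were compared with the ESC HEB list. The overlap code was tested on simulated lists. With 80.1% of 4108 simulated ESC SMAD2/3 regions planted on ESC HEB regions, and 24.7% of 18903 simulated Endoderm HEB regions planted on Endoderm+SB HEB regions, 100% of the planted overlaps were recovered, and bedtools counted the same overlaps for all ordered pairs of the 6 lists.

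Gene lists were fixed before the data were examined. They were the Nodal/activin pathway and its known targets (25 genes), pluripotency (20), definitive endoderm (20), mesoderm (23), neuroectoderm (23), developmental regulators known as targets of Polycomb repressive complex 2 (PRC2) (35), PRC2 and PRC1 members (16), E proteins and Id factors (7), extraembryonic and trophoblast genes (14), housekeeping genes (14) and Olfr, Vmn1r and Vmn2r receptors (1463). Membership came from general knowledge, not from Polycomb data of these cells, and the regulator list includes Bmi1, itself a PRC1 gene. Cer1 is on the Nodal/activin and definitive endoderm lists, Cdx2 on the regulator and extraembryonic lists, and Hand1 on the mesoderm and extraembryonic lists. The number of members with a region was set beside 10000 random lists of the same size drawn from 21900 protein-coding genes. These were matched neither on gene length nor on clustering, and long genes collect more regions and clustered genes, as the 13 Hox genes on these lists, can share them, so the random lists only describe these libraries.

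Genes named in the text follow a rule fixed before the data were examined. It takes the genes at the 10 regions of each library with the highest tag enrichment, those at the 5 highest regions shared by each pair of lists and the 5 highest of each list alone, and up to 4 members of each gene list per library in order of their highest tag enrichment. Members without a region may be named as such. Results for a few genes that the rule takes are not reported here. Members listed by name beyond the first 4, as those found in both lists or in 1 list alone, were chosen after their values were seen. Tag enrichment is the authors' value and was used only to describe, rank or filter regions within a list. Ranks from lists of different lengths show no change, and the values were not compared between lists.

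Alternatives planned before the data were examined were a reciprocal overlap of 50%, summits within 200 bp, the upper 50% of each list by tag enrichment, lists limited to the 4111 highest regions each, autosomes only, regions closer than 500 bp merged, and assignment within 2 kb of a 5′ end. Assignment within 50 kb was not run, because the deposited gene column reaches only 1 kb. Chosen after seeing the data were a ChIP height of at least 28 in every list, regions beyond 1 kb of a 5′ end, omission of regions with an input density over 5 times the list median, standardization over quintiles of ChIP height or over promoter-proximal position, and the highest quintile of ChIP height alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. Total read numbers of the libraries were not used here, so depth is given as the tags inside the listed regions.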

Results

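Binding of HEB and of SMAD2/3 was profiled by ChIP-seq in mouse ESCs and in endoderm derived from them with Activin A, with HEB also profiled in both after SB431542. HEB is a basic helix-loop-helix E protein, and SMAD2 and SMAD3 are the transcription factors that carry Nodal and activin signals to DNA. The 6 groups had 1 ChIP library each, so the differences below compare these libraries and have no replicate check. The lists held 4111 regions for ESC SMAD2/3, 17222 for ESC HEB, 16769 for ESC+SB HEB, 11033 for Endoderm SMAD2/3, 18981 for Endoderm HEB and 10147 for Endoderm+SB HEB. The ESC SMAD2/3 list held 933126 ChIP tags over 2383 kb, the smallest total, and the Endoderm HEB list 5051930 tags over 11121 kb, the largest. The median region held between 155 (Endoderm+SB HEB) and 184 (ESC+SB HEB) ChIP tags, against 15 (Endoderm HEB) to 31 (ESC+SB HEB) input tags. Because the lists differ in length and in the tags behind them, their lengths alone show no difference in binding.

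Promoter-proximal regions made up 15.2% of the ESC SMAD2/3 list (95% CI 14.1 to 16.3), 17.7% of ESC HEB (17.2 to 18.3) and 15.1% of Endoderm HEB (14.6 to 15.6). They made up 28.4% of ESC+SB HEB (27.7 to 29.1), 30.3% of Endoderm SMAD2/3 (29.5 to 31.2) and 34.5% of Endoderm+SB HEB (33.5 to 35.4). In every list this share was larger among regions of low ChIP height than among those of high ChIP height, at 23.7% against 7.40% in the lowest and highest quintile of Endoderm HEB and 46.2% against 10.7% in those of Endoderm+SB HEB. By quintile of tag enrichment the fall was steeper, from 40.8% in the lowest to 4.24% in the highest of Endoderm HEB. In Endoderm+SB HEB it was from 67.9% to 5.52%. Lists shortened by tag enrichment, as those of equal length below, therefore lost promoter-proximal regions more than others. Regions with no gene listed ranged from 37.3% (Endoderm+SB HEB) to 48.1% (ESC SMAD2/3).

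**Figure D1:**
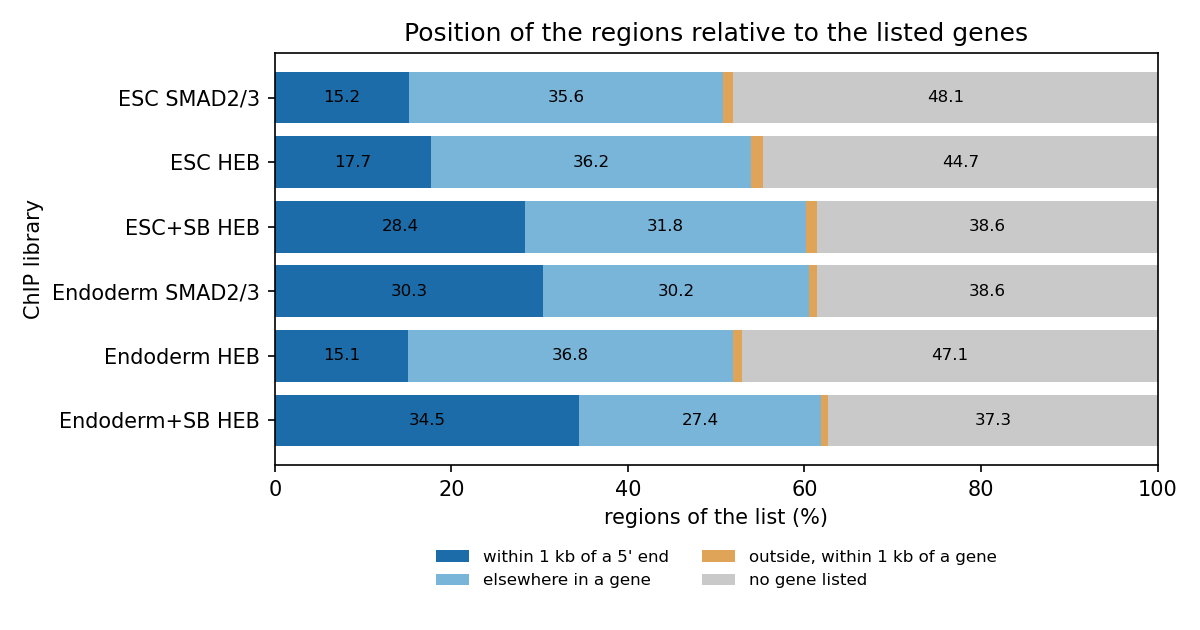
Position of the regions of each list relative to the listed genes, as stacked bars whose length is the percent of regions of the list (1 library per bar, no error drawn). Promoter-proximal shares were 15.1% to 17.7% in ESC SMAD2/3, ESC HEB and Endoderm HEB and 28.4% to 34.5% in the other lists.

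The first comparison asked where HEB and SMAD2/3 bind together in ESCs. Of the 4111 SMAD2/3 regions, 3448 (83.9%, 95% CI 82.7 to 85.0) overlapped a HEB region, against a mean of 0.903% and a maximum of 2.16% over the rotations. Genes of the Nodal/activin pathway had regions in both lists. Tdgf1, which encodes the Nodal co-receptor Cripto, had a SMAD2/3 region at chromosome 9, 110849485 to 110850917, 823 bp from the 5′ end, with 2526 ChIP and 73 input tags and a tag enrichment of 34.6. Skil and Ski, which encode repressors of SMAD signalling, had enrichments of 32.3 (chromosome 3, 30992945 to 30994529, at the 5′ end) and 29.1 (chromosome 4, 154563504 to 154564764, inside the gene). In the HEB list of ESCs the high Nodal/activin members included Ski (38.7), Lefty1, which encodes a Nodal inhibitor (24.3, chromosome 1, 182863286 to 182865640, at the 5′ end), and Tdgf1 (23.1). This HEB region of Ski (chromosome 4, 154537212 to 154538570) lay apart from its SMAD2/3 region named above.

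Of the 25 Nodal/activin genes, 13 had a SMAD2/3 region in ESCs (random lists, median 2 and highest 10) and 17 had a HEB region (median 6 and highest 15). At 11 of them a HEB region overlapped a SMAD2/3 region, and Bambi had SMAD2/3 without HEB. Of the 20 pluripotency genes, 12 had SMAD2/3 (median 1, highest 7), all 12 of them with an overlapping HEB region, and 18 had HEB (median 5, highest 12). Esrrb, a nuclear receptor of the pluripotency network, had 17 HEB regions, the highest with 1053 ChIP and 17 input tags (chromosome 12, 87807088 to 87807639, enrichment 61.9). Its highest SMAD2/3 region reached 20.1 and lay elsewhere in the gene (87842458 to 87843301). SMAD2/3 regions were also listed at Pou5f1, the gene of the pluripotency factor OCT4 (17.5, chromosome 17, 35641490 to 35642435, 549 bp from the 5′ end), at Tfcp2l1 (15.5) and over the 5′ end of Nanog (14.9, chromosome 6, 122657100 to 122657710). In the HEB list Utf1 (23.2), Tfcp2l1 (21.6) and Nanog (21.4) followed Esrrb, and Klf4 and Klf5 had neither factor.

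Genes of later lineages were listed more often for HEB than for SMAD2/3 in ESCs, where random lists of the same sizes also held few SMAD2/3 genes. Definitive endoderm genes had SMAD2/3 at 0 of 20 (median 1) and HEB at 12 (median 5), led by Foxa1 (19.9), Gata4 (15.9), Lhx1 (15.6) and Foxa2 (15.3), which encode transcription factors of endoderm and axial mesendoderm. Mesoderm genes had SMAD2/3 at 2 of 23 (median 1.5), Wnt3a and Wnt3, and HEB at 15 (median 5), led by Snai1, a regulator of epithelial-mesenchymal transition (83.6, chromosome 2, 167365305 to 167366607, 2592 ChIP and 31 input tags), Hand2 (16.5), Hand1 (15.5) and Tbx5 (14.5). Neuroectoderm genes had SMAD2/3 at 3 of 23 (Pax6, Nes and Pax7, median 1.5) and HEB at 21 (median 5), led by Zic1 (37.0), Zic2 (31.0), Neurod1 (25.3) and Pax6 (23.5). Of the 35 PRC2-bound regulators 0 were assigned a SMAD2/3 region in ESCs (median 2) and 31 a HEB region (median 8, highest 19). At Hoxa13, singled out after its values were seen, a HEB region overlapped a SMAD2/3 region with no gene listed. Among these, Bmi1 reached 46.7 (chromosome 2, 18605641 to 18606124), Hoxb2 34.1 (chromosome 11, 96213123 to 96215219), Pax9 33.2 (chromosome 12, 57795214 to 57799142) and Hoxc9 24.3 (chromosome 15, 102805240 to 102809568). Bmp2, Hoxc4, Hoxd1 and Sim1 had neither factor. HEB regions outnumbered SMAD2/3 regions, and 19.8% of them (3414 regions) overlapped SMAD2/3, Tiam2 (139) being the highest listed gene among those that did not. SMAD2/3 regions without HEB numbered 663, among them regions in Ppap2a (66.4) and Akap6 (37.5).

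SMAD2/3 regions of ESCs overlapped HEB in 76.4% of the lowest quintile of ChIP height and 92.1% of the highest, and in 72.8% of promoter-proximal and 85.9% of other regions. The overlap came to 33.3% when each list was limited to its 4111 highest regions. At that length the ESC HEB list held 8 Nodal/activin and 11 pluripotency genes, fewer than the 13 and 12 of SMAD2/3, beside 6 definitive endoderm genes and 18 PRC2-bound regulators.

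**Figure D2:**
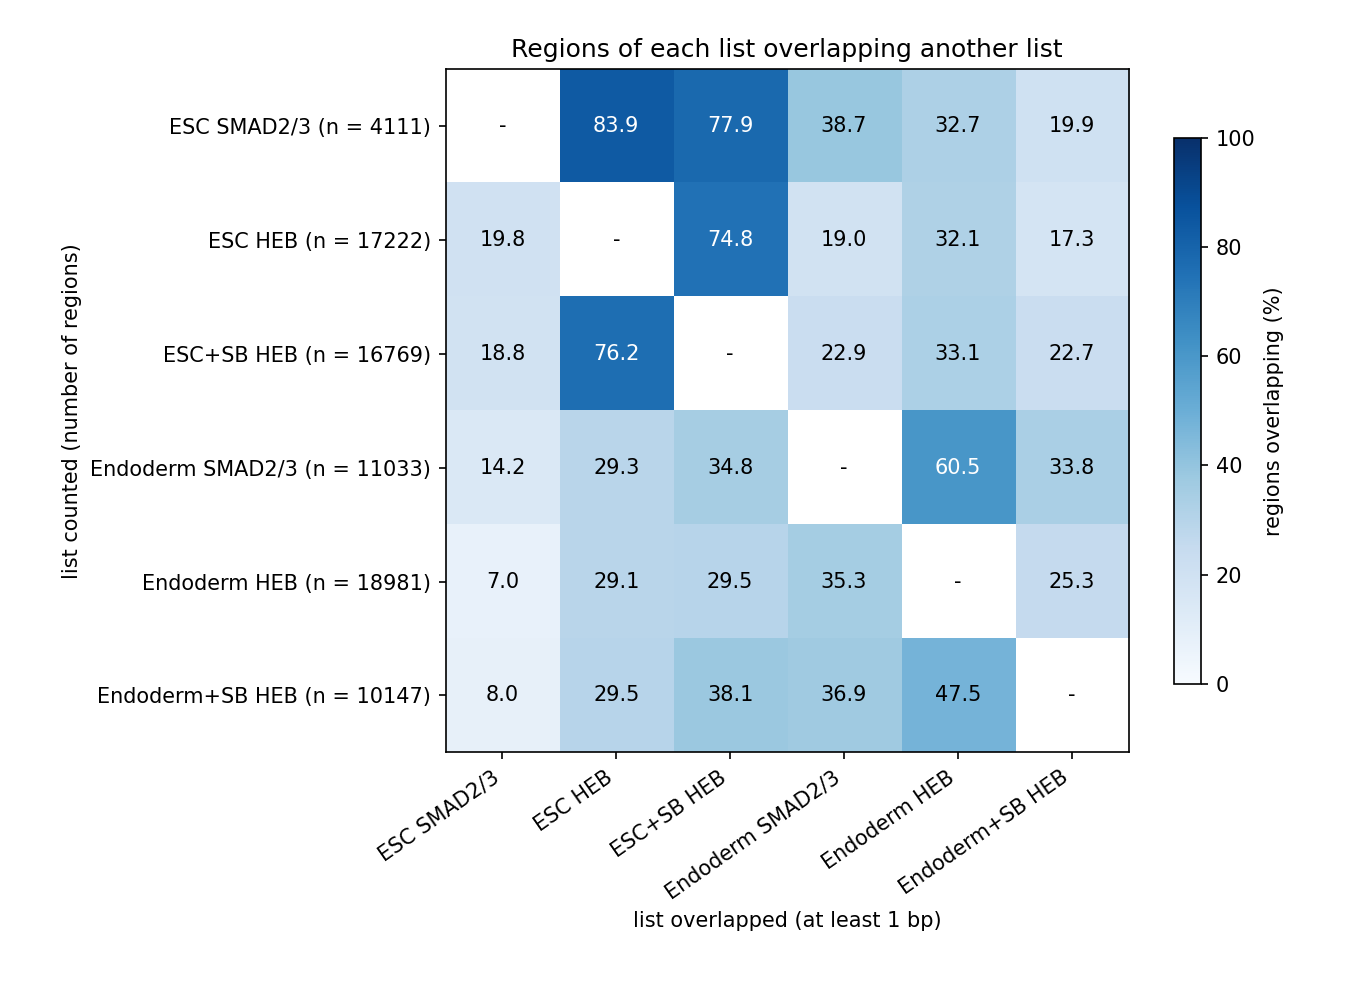
Percent of the regions of each list (vertical axis, with its number of regions) that overlap a region of another list (horizontal axis) by at least 1 bp, with the percent written in each cell (1 library per list). ESC SMAD2/3 regions overlapped ESC HEB in 83.9%, and Endoderm SMAD2/3 regions overlapped Endoderm HEB in 60.5%.

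In endoderm, 6679 of 11033 SMAD2/3 regions (60.5%, 95% CI 59.6 to 61.5) overlapped a HEB region, against a rotation mean of 0.958% and maximum of 1.95%. Skil (96.2, chromosome 3, 30992519 to 30995167), Pmepa1, a feedback inhibitor of the pathway (74.4, chromosome 2, 173101855 to 173102802), and Nodal itself (66.6, chromosome 10, 60880503 to 60882523) had SMAD2/3 regions over their 5′ ends. The highest HEB regions on the Nodal/activin list were those of Cer1, which encodes a secreted Nodal antagonist (40.8, chromosome 4, 82530494 to 82532746, at the 5′ end), Lefty1 (34.5), Ski (32.1) and Skil (30.6). Of the 25 Nodal/activin genes 18 had SMAD2/3 and 17 had HEB (random medians 6 and 6), with 15 in both and 14 overlapping. Acvr1b, Fst and Lefty2 had SMAD2/3 alone.

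Definitive endoderm genes carried both factors in endoderm. SMAD2/3 was at 13 of 20, all 13 with an overlapping HEB region, and HEB was at 19 (random median 5 for each), an order that turned to 12 and 9 with lists of equal length. Eomes, a T-box factor required for definitive endoderm, had a SMAD2/3 region 8076 bp from its 5′ end (chromosome 9, 118395383 to 118397135, 24.5) and a HEB region at the same place (118395393 to 118397094, 2121 ChIP and 61 input tags, 34.8). Gata6, which encodes a zinc finger factor of endoderm, had SMAD2/3 at 32.4 (chromosome 18, 11060101 to 11060512) and HEB at 33.9. Gsc (30.2) and Prdm1 (24.1) completed the highest SMAD2/3 members, and Cer1 (40.8) and Prdm1 (31.9) the highest HEB members. Genes with HEB alone included Dkk1, Foxa3, Hhex, Hnf4a and Sox17, and Sox7 had neither.

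Extraembryonic genes had regions at 8 (SMAD2/3) and 10 (HEB) of 14 in endoderm (random medians 3 and 3), among them Dab2 (30.5) and Krt8 (12.0) for SMAD2/3 and Krt8 (37.8) and Sparc (21.6) for HEB. Mesoderm genes had SMAD2/3 at 7 of 23 and HEB at 16 (random medians 5 and 6), with Wnt3 (19.0) first for SMAD2/3 and Snai1 (75.3) and Kdr (41.0) first for HEB. Neuroectoderm genes had SMAD2/3 at 9 of 23 and HEB at 18 (random medians 5 and 6), and the highest were Zic2 (26.3) and Pax7 (24.8) for SMAD2/3 and Pax3 (73.8) and Pax7 (48.1) for HEB. PRC2-bound regulators had SMAD2/3 at 6 of 35 and HEB at 23 (random medians 8 and 9). Pax9 (13.0), Pax2 (11.0), Lhx9 (10.9) and Evx1 (8.19) were the highest of these for SMAD2/3, and Bmi1 (41.4), Nkx6-1 (19.98), Pax2 (17.2) and Nkx2-2 (15.6) for HEB. SMAD2/3 regions without HEB were more often promoter-proximal (41.8%, 95% CI 40.4 to 43.3) than those with HEB (22.8%, 21.8 to 23.9), and included regions in Vmn2r3 (59.3) and Fam188b (55.2). Ttc7b (124) and Zc3h12c (107) held the highest genic HEB regions without SMAD2/3. With lists of equal length the endoderm overlap was 32.1%, and extraembryonic genes numbered 4 for SMAD2/3 and 3 for HEB.

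HEB was next compared between ESCs and endoderm. Of the 17222 ESC HEB regions, 5534 (32.1%, 95% CI 31.4 to 32.8) overlapped an Endoderm HEB region, against a rotation mean of 0.976% and maximum of 1.61%, and 5518 of 18981 Endoderm HEB regions (29.1%, 28.4 to 29.7) overlapped ESC HEB. Among pluripotency genes 10 had HEB in both, and 8 had it in ESCs alone (Dppa3, Dppa5a, Fgf4, Klf2, Nr0b1, Prdm14, Tfcp2l1 and Zfp42). None had it in endoderm alone. The 10 included Esrrb, Pou5f1, Lin28a and Tbx3, with enrichments of 31.1, 27.96, 27.2 and 22.3 in endoderm. Among definitive endoderm genes 12 had HEB in both and 7 in endoderm alone (Cer1, Cxcr4, Foxa3, Frzb, Hhex, Hnf4a and Mixl1). PRC2-bound regulators had HEB in both at 21, in ESCs alone at 10 and in endoderm alone at 2 (Bmp2 and Sim1). The 10 included Evx2, Gbx2, Hoxa13, Hoxa9, Hoxb1, Hoxb13, Hoxb9, Hoxd9 and Wnt1. Neuroectoderm genes had HEB in both at 17.

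The highest HEB regions found in both states were intergenic (chromosome 17, 28525116 to 28526081, enrichment 227 in ESCs, and chromosome 2, 154251723 to 154254310, 198) or lay in Cbfa2t2 (chromosome 2, 154291601 to 154292290, 169) and Tiam2. Ubxn11 (135), Nkain3 (84.9) and Meis2 (81.7) held the highest genic regions of ESCs alone, and Xrcc4 (130.0) and Map3k7 (113) those of endoderm alone. Promoter-proximal ESC HEB regions overlapped Endoderm HEB in 51.1% and the others in 28.04%. With equal list lengths the overlap was 16.8%, and the PRC2-bound regulators with HEB numbered 18 in ESCs and 2 in endoderm.

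SMAD2/3 was compared between the same states. Of the 4111 ESC regions 1590 (38.7%, 95% CI 37.2 to 40.2) overlapped an endoderm SMAD2/3 region, against a rotation mean of 0.577%, and 1567 of 11033 endoderm regions (14.2%, 13.6 to 14.9) overlapped ESC SMAD2/3. All 13 Nodal/activin genes with SMAD2/3 in ESCs had an overlapping region in endoderm, and Acvr1b, Cer1, Fst, Ltbp1 and Smad3 had one in endoderm alone. At equal list length, however, these genes numbered 13 in ESCs and 12 in endoderm. Pluripotency genes had SMAD2/3 in both at 5 (Esrrb, Nanog, Pou5f1, Tbx3 and Utf1), in ESCs alone at 7 and in endoderm alone at 4 (Klf4, Lin28a, Sall4 and Sox2). The highest of the 9 in endoderm were Pou5f1 (33.2), Esrrb (19.6), Utf1 (13.4) and Sall4 (13.3). Definitive endoderm genes had it in endoderm alone, at 13 of 20. Among the highest shared regions was the one in Ppap2a, and Zmynd8 (39.2) held the highest genic region of ESCs alone. The overlap at equal length was 19.2%.

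Endoderm SMAD2/3 regions absent from the ESC SMAD2/3 list were asked for HEB in ESCs. Of these 9466 regions, 2030 (21.4%, 95% CI 20.6 to 22.3) overlapped ESC HEB, 23.7 times the rotation mean of 0.904%, whose maximum was 1.33%. All ordered pairs of whole lists had a higher ratio, the lowest being 31.5 for ESC HEB with Endoderm SMAD2/3. The ratio therefore does not show that HEB marks later SMAD2/3 sites in particular. HEB of endoderm overlapped 5656 (59.8%). HEB was listed in both states at 1644, in ESCs alone at 386, in endoderm alone at 4012 (42.4%) and in neither at 3424. Of the 13 definitive endoderm genes with SMAD2/3 in endoderm, 9 had an ESC HEB region that overlapped at least 1 of their SMAD2/3 regions (Eomes, Foxa1, Foxa2, Gata4, Gata6, Gsc, Lhx1, Otx2 and Prdm1), and Cer1, Cxcr4, Frzb and Mixl1 had none. This was not always the SMAD2/3 region of highest tag enrichment named above. The only ESC HEB regions of Gata6 (chromosome 18, 11051189 to 11053965) and Prdm1 (chromosome 10, 44178280 to 44178923) lay apart from it. The share was 10.0% with the upper 50% of each list and 3.68% with lists of equal length.

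HEB was then compared with and without inhibition of the activin and Nodal receptors in ESCs. Of the 17222 ESC HEB regions 12888 (74.8%, 95% CI 74.2 to 75.5) overlapped an ESC+SB HEB region, against a rotation mean of 0.976% and maximum of 2.14%, and 76.2% (75.5 to 76.8) of ESC+SB HEB regions overlapped ESC HEB. All 31 PRC2-bound regulators with HEB had an overlapping region with SB, and Bmp2 and Hoxc4 had one with SB alone. Bmi1 (81.9, chromosome 2, 18605638 to 18606251, 918 ChIP and 11 input tags), Hoxb2 (35.5), Pax9 (33.8) and Nkx6-1 (25.5) were the highest with SB. All 12 definitive endoderm genes with HEB had it with SB, and Cxcr4 was added. Lhx1 (17.1) and Foxa1 (16.6) were highest. Pluripotency genes were shared at 17 of 18, Dppa5a being the exception, with Esrrb (52.2) and Tdh (26.3) highest with SB. Neuroectoderm genes were shared at 20 of 21, all but En1, with Zic1 at 30.2, and mesoderm genes at 13 of 15, all but Snai2 and Wnt3, with Snai1 at 33.4. These orders turned with lists of equal length, to 12 without and 15 with SB for neuroectoderm and 7 and 9 for mesoderm genes, and with the upper 50% of each list, to 17 and 20 and to 10 and 12. On the Nodal/activin list HEB was in both at 13, including Ski (21.2 with SB). Fst, Lefty1, Lefty2 and Ltbp1 were assigned HEB only without SB, and Acvr2b, Bambi and Inhbb only with SB. The Lefty1 region (182863286 to 182865640, ChIP height 449, over the 5′ end) overlapped a shorter one with SB (182863775 to 182864143). The shorter region had no gene listed, so by the 1 kb rule it did not reach the 5′ end. At equal length 8 Nodal/activin genes had HEB without and 9 with SB.

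Regions of the lowest quintile of ChIP height without SB were listed with SB in 48.1% and those of the highest in 98.3% (97.8 to 98.7). The region of 5730410E15Rik (50.0) was the highest genic one without a counterpart. Regions listed only with SB were promoter-proximal in 51.9% (50.4 to 53.5), against 21.0% (20.3 to 21.7) of the others. The ESC+SB HEB list also had a higher smallest ChIP height than the others. The only ESC HEB regions of En1 (ChIP height 27.6), Snai2 (25.9) and Ltbp1 (26.1) lay below it. Regions of such height could not be listed with SB. Those of Wnt3 (28.1) and Fst (28.2) lay just above it, and Lefty2 (29.2) and a Dppa5a region (48.1) higher. Absence of En1, Snai2, Ltbp1, Wnt3 and Fst with SB therefore does not show lost HEB. With a ChIP height of at least 28 in every list, neuroectoderm genes numbered 20 without and 20 with SB, and mesoderm genes 14 and 13.

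In the differentiating cells a smaller part of the HEB regions was listed with SB. Of the 18981 Endoderm HEB regions 4796 (25.3%, 95% CI 24.7 to 25.9) overlapped an Endoderm+SB HEB region, against a rotation mean of 0.507% and maximum of 0.817%, and 47.5% (46.5 to 48.5) of the Endoderm+SB HEB regions overlapped Endoderm HEB. Definitive endoderm genes with HEB numbered 19 without and 6 with SB. Eomes, Frzb, Gata4, Gsc, Lhx1 and Otx2 had it in both, and Cer1, Cxcr4, Dkk1, Foxa1, Foxa2, Foxa3, Gata6, Hhex, Hnf4a, Mixl1, Prdm1 and Sox17 were among those assigned it only without SB. The Foxa1 region overlapped one with SB that had no gene listed. The only Endoderm HEB regions of Foxa3 (ChIP height 25.2) and Cxcr4 (26.0) lay near the smallest listed height of 25.0. So did that of Smad4 (25.3) on the Nodal/activin list below. Absence of these genes with SB therefore does not show lost HEB. The Cer1 region (622) and a Foxa2 region (115) were far higher. Frzb, which encodes a secreted Wnt antagonist, was highest with SB (37.3, chromosome 2, 80288312 to 80288901), followed by Eomes (22.3), Otx2 (11.9) and Gsc (11.0). On the Nodal/activin list 10 genes had HEB in both, Cer1, Foxh1, Lefty1, Nodal, Pmepa1, Smad4 and Tdgf1 only without SB, and Acvr1b and Acvr2b only with SB. Ltbp1 (29.6), Tgif1 (15.6) and Smad6 (13.9) were among the highest with SB. Extraembryonic genes with HEB numbered 10 without and 1 with SB (Sparc, 7.88). Mesoderm genes numbered 16 without and 5 with SB, with Tbx5 (14.9) highest, and pluripotency genes 10 and 5, where Lin28a (41.3) and Sall4 (22.0) were highest.

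Neuroectoderm genes numbered 18 without and 17 with SB, 14 of them in both, and those found only with SB included Neurog1 and Neurog2, proneural transcription factor genes. The highest with SB were Pax3 (53.5, chromosome 1, 78178412 to 78178854), Emx2 (42.0, chromosome 19, 59540387 to 59540925), Pax6 (32.0, chromosome 2, 105527582 to 105529184) and Pax7 (31.5). PRC2-bound regulators with HEB numbered 23 without and 12 with SB, the 12 all being in both and led by Bmi1 (26.8) and Pax2 (21.2). With lists of equal length the directions differed: these regulators numbered 2 without and 6 with SB, neuroectoderm genes 4 and 10, definitive endoderm genes 9 and 4, and mesoderm genes 4 and 4.

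Regions found in both included those in Xrcc4, Bcl2l1 (112), Gse1 (112) and Tet3 (101), and regions only without SB those in Ttc7b and Map3k7. Cadps (74.9, chromosome 14, 13222157 to 13222621) and Lrba (67.8) held the highest genic regions found only with SB. The one in Cadps lay directly beside another Cadps region with SB (13221363 to 13222134, 70.5) that overlapped Endoderm HEB, so it marks no separate site. Atp8a2 (96.6, chromosome 14, 60355511 to 60357177) held the highest region of the Endoderm+SB HEB list, which also overlapped Endoderm HEB. Regions kept with SB were promoter-proximal in 33.6% (32.3 to 34.99) and those not kept in 8.84% (8.38 to 9.32). The share kept was 21.4% in the lowest quintile of ChIP height and 34.7% (33.2 to 36.3) in the highest. It was 16.0% with the upper 50% of each list.

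**Figure D3:**
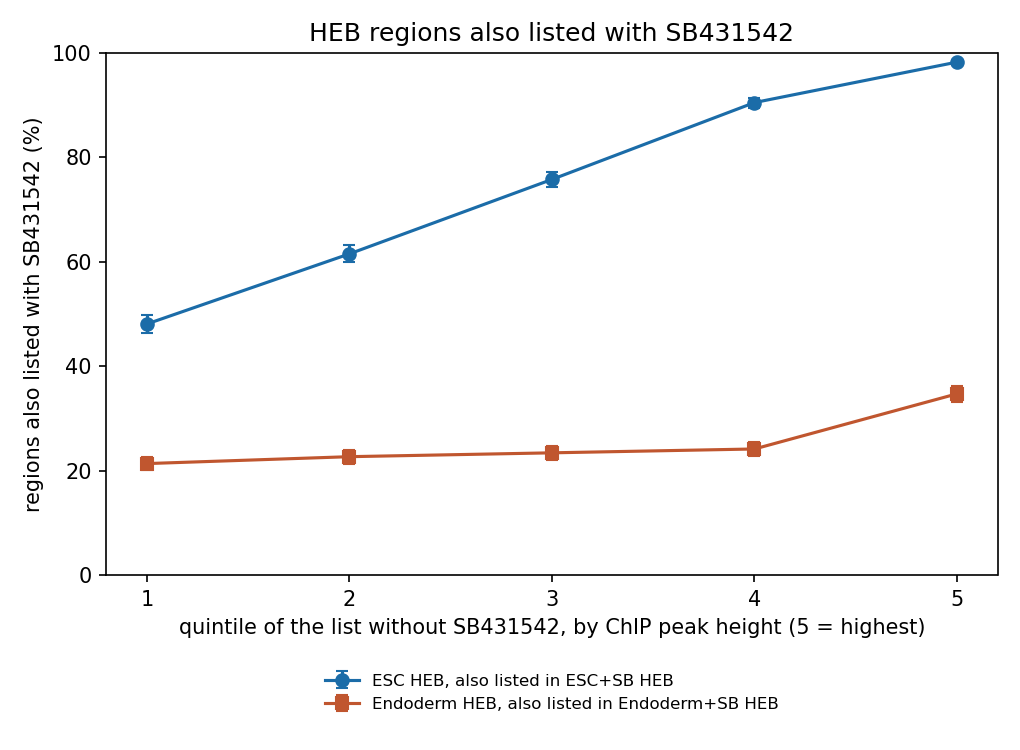
Percent of HEB regions also listed with SB431542 (vertical axis) by quintile of ChIP peak height in the list without SB431542 (horizontal axis, 5 the highest), in ESCs (circles) and endoderm (squares), with exact 95% intervals as bars. The share went from 48.1% to 98.3% in ESCs and from 21.4% to 34.7% in endoderm.

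HEB regions that overlapped SMAD2/3 were listed with SB more often than the other HEB regions in both states. In ESCs 3043 of 3414 co-bound regions (89.1%, 95% CI 88.0 to 90.2) and 9845 of 13808 other regions (71.3%, 70.5 to 72.1) were kept, a difference of 17.8 percentage points (16.5 to 19.1). In endoderm 2887 of 6704 co-bound regions (43.1%, 41.9 to 44.3) and 1909 of 12277 others (15.5%, 14.9 to 16.2) were kept, a difference of 27.5 points (26.2 to 28.9). Standardized over quintiles of ChIP height, the ESC difference was 1.84 points. In endoderm co-bound regions were kept more often in each quintile of ChIP height. They were kept at 43.4% against 14.5% in the lowest and at 43.0% against 21.7% in the highest. With lists of equal length the endoderm difference was 13.6 points, while the ESC difference was not reduced.

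The remaining gene lists served as comparisons. Members of PRC2 and PRC1 had a region at 3 of 16 in ESC SMAD2/3 (Mtf2, Cbx7 and Pcgf2), 10 in ESC HEB, 11 in ESC+SB HEB, 8 in Endoderm SMAD2/3, 10 in Endoderm HEB and 8 in Endoderm+SB HEB, and at equal list length 3, 4, 2, 1, 3 and 3. Jarid2, which encodes a PRC2 cofactor, was among the highest with 18.8 in ESC HEB and 41.7 in Endoderm+SB HEB (chromosome 13, 44850504 to 44851413). The 7 E protein and Id genes had regions at 1, 4, 6, 3, 5 and 6 in the same order, and Id1, which encodes an inhibitor of E proteins, was highest in each HEB list, with 31.9 in ESC HEB and 29.6 in Endoderm HEB. Tcf12, the HEB gene itself, had a region in ESC+SB HEB (5.88, at the 5′ end), Endoderm SMAD2/3 (10.8, at the 5′ end) and Endoderm+SB HEB (18.7). Extraembryonic genes in ESCs had SMAD2/3 at 1 of 14 (Krt8) and HEB at 5 without and 8 with SB. Housekeeping genes had regions at 2, 4, 9, 3, 6 and 6 of 14, with random medians of 1 to 4. ESC SMAD2/3 was at Actb and Gapdh, ESC HEB at Ywhaz (8.22), Tbp, Gapdh and Actb, and Endoderm SMAD2/3 among others at Ywhaz and Actb. Of 1463 Olfr, Vmn1r and Vmn2r receptor genes, at most 5 had a region in any list. They were Olfr56, Vmn2r57, Vmn2r75 and Vmn2r99 in ESC HEB, the same genes except Vmn2r75 in ESC+SB HEB, Vmn2r3 in Endoderm SMAD2/3, and Olfr535, Olfr576, Vmn2r2, Vmn2r23 and Vmn2r24 in Endoderm HEB.

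**Figure D4:**
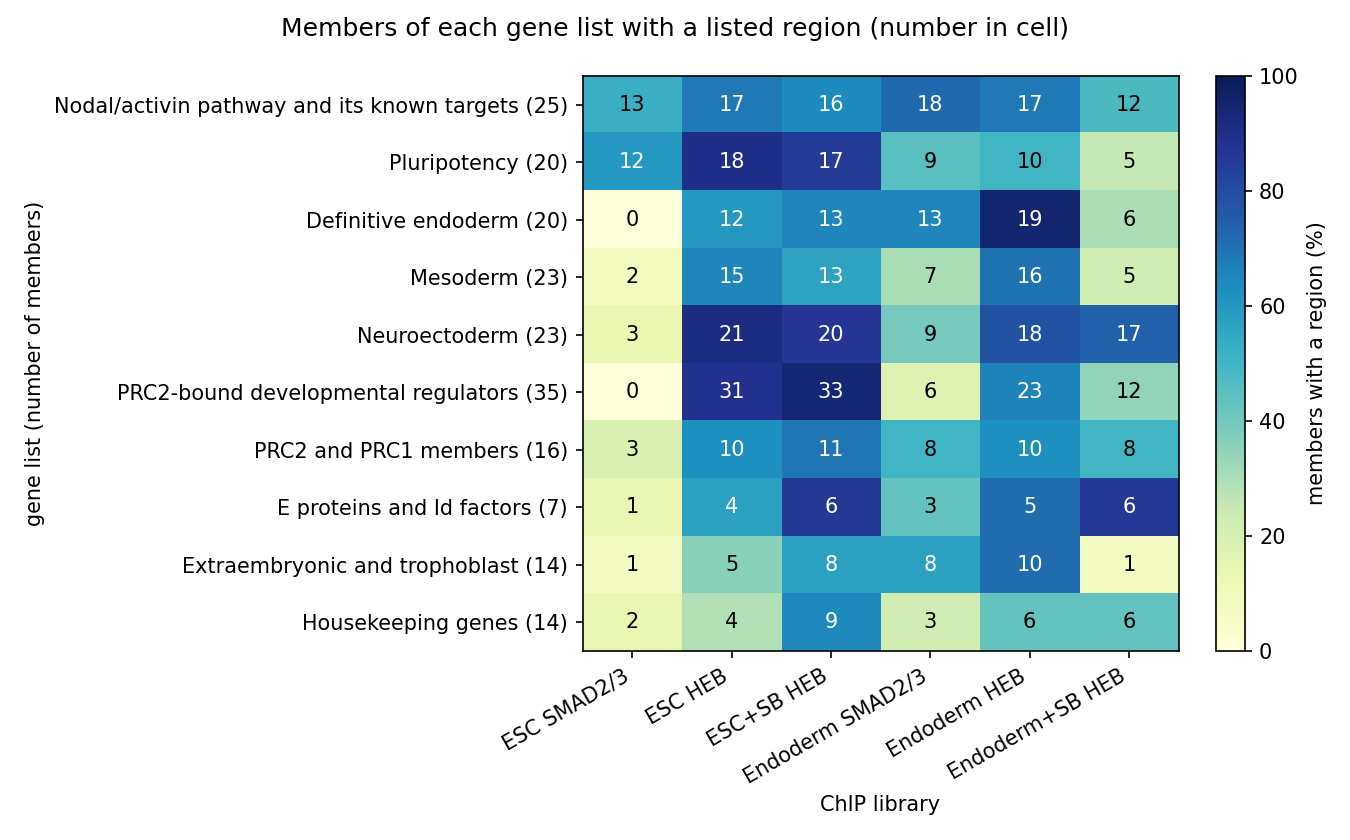
Number of genes of each list (vertical axis, list size in brackets) with a region in each library (horizontal axis), written in each cell and shaded by the percent of the list (1 library per column). Among PRC2-bound regulators 31 of 35 were assigned a region in ESC HEB and 0 in ESC SMAD2/3, and among definitive endoderm genes 19 of 20 had one in Endoderm HEB and 6 in Endoderm+SB HEB.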

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

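All 3 tests reported for the endoderm regions below were chosen only after the result was seen. The number of gene list members with a HEB region moved in opposite directions with SB in ESCs and in endoderm for 4 lists, and for none of them was the difference tested, since each group had 1 library. Definitive endoderm genes went from 12 to 13 in ESCs and from 19 to 6 in endoderm, a difference of 14 members between these changes, and at equal list length from 6 to 9 and from 9 to 4. PRC2-bound regulators went from 31 to 33 and from 23 to 12, a difference of 13, but at equal list length from 18 to 27 and from 2 to 6, so the opposite direction was lost. That cut kept the regions of highest tag enrichment, seldom promoter-proximal, from endoderm lists of 18981 and 10147 regions. It is therefore no neutral control for these counts. Extraembryonic and trophoblast genes went from 5 to 8 and from 10 to 1, a difference of 12, and at equal list length from 2 to 2 and from 3 to 0. PRC2 and PRC1 members went from 10 to 11 and from 10 to 8, a difference of 3, and at equal list length from 4 to 2 and from 3 to 3.

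Signal also appeared on the mitochondrial chromosome, which no comparison addressed. The Endoderm+SB HEB list held 2 mitochondrial regions (positions 1 to 6520 and 10922 to 15772) with 143023 ChIP tags against 59152 input tags, a ratio of 2.42, and the other lists held none. Their input density was 167 times the autosome median of that list, so tags there are high without antibody. The ratio was below the list's median tag enrichment of 9.33. Whether such regions were filtered from the other lists is not given, and binding of HEB there is not shown.

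The low share of endoderm HEB regions listed with SB (25.3%, against 74.8% in ESCs) was weighed against technical and biological explanations. As read from the labels, SB was given for 48 hours in the differentiating cells and for 24 hours in ESCs. Exposure time therefore cannot be told apart from cell type in comparisons with ESCs. A lower depth or weaker pull-down in the Endoderm+SB HEB library would remove low peaks first and leave the highest, yet of the quintile of endoderm HEB regions with the highest ChIP peaks only 34.7% (95% CI 33.2 to 36.3) was listed with SB, which argues against it as the whole cause. A poorer ChIP in which signal shifts to promoters would place the regions found only with SB there, and 35.6% (34.3 to 36.9) of them were promoter-proximal, from 49.3% in the lowest quintile of ChIP height to 7.02% in the highest, where the whole list had 10.7%, so this stays open. Other cells or another cell state with SB would bring strong regions that are absent without it, and 37.2% of the highest quintile with SB had no counterpart without it, against 0.328% in ESCs. This is consistent with a different cell population after SB, but with 1 library per group a culture that differed for other reasons may give the same, and an effect of the inhibitor on HEB itself cannot be told apart from a change of cell state.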

How the results depend on the processing

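The 2 differences between co-bound and other regions kept their sign under every alternative run on them, but the order of many member counts turned. Between ESC HEB without and with SB it turned at equal list length for Nodal/activin genes (from 17 and 16 to 8 and 9), mesoderm (15 and 13 to 7 and 9), neuroectoderm (21 and 20 to 12 and 15) and PRC2/PRC1 members (10 and 11 to 4 and 2). With the upper 50% of each list it turned for mesoderm (10 and 12), neuroectoderm (17 and 20) and E protein or Id genes (4 and 6 to 4 and 3), and with a ChIP height of at least 28 for pluripotency (18 and 17 to 15 and 17). Between Endoderm HEB without and with SB it turned at equal length for PRC2-bound regulators (23 and 12 to 2 and 6) and neuroectoderm (18 and 17 to 4 and 10). Between ESC and Endoderm HEB it turned for mesoderm (15 and 16 to 7 and 4 at equal length, 14 and 13 at the height limit) and E protein or Id genes (4 and 5 to 4 and 2 with the upper 50%). Equal length also turned ESC against Endoderm SMAD2/3 for Nodal/activin (13 and 18 to 13 and 12), mesoderm (2 and 7 to 2 and 1), PRC2/PRC1 (3 and 8 to 3 and 1) and housekeeping genes (2 and 3 to 2 and 1). It turned ESC SMAD2/3 against HEB for Nodal/activin (13 and 17 to 13 and 8), pluripotency (12 and 18 to 12 and 11) and housekeeping genes (2 and 4 to 2 and 0). In endoderm it turned SMAD2/3 against HEB for pluripotency (9 and 10 to 7 and 5, and 8 and 7 within 2 kb), definitive endoderm (13 and 19 to 12 and 9), extraembryonic (8 and 10 to 4 and 3) and housekeeping genes (3 and 6 to 1 and 0, as with the upper 50%). Of the values obtained under the alternatives, 208 stayed within their 95% interval, or for counts within 1.5 times, and 154 moved beyond it. Every result run with autosomes only or with regions of high input density left out kept to that margin, as did the region numbers with regions closer than 500 bp merged. Assignment within 50 kb of a 5′ end was not run, because the deposited gene column reaches 1 kb. No paired analysis was possible because each group held 1 library. The ChIP height limit, the restriction to regions beyond 1 kb, the input density limit, the standardization over height or position and the highest quintile were chosen after seeing the data. Where lists were shortened, the lower shares and counts follow at least in part from the smaller number of regions, and for the other moves the cause was not tested. Equal length and the upper 50% also removed promoter-proximal regions more than others, and equal length removed a larger part of the longer lists. Turned orders under these settings may reflect this. Depth limits every list, since a region below the height limit is not listed and an absent region does not show absent binding.

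Values are given in the order ESC SMAD2/3 with ESC HEB, Endoderm SMAD2/3 with Endoderm HEB, ESC HEB with Endoderm HEB, ESC with Endoderm SMAD2/3, ESC HEB with SB, Endoderm HEB with SB, the difference between co-bound and other regions kept with SB in ESCs and then in endoderm, and endoderm SMAD2/3 regions absent from ESCs with ESC HEB. A reciprocal overlap of 50% gave 73.6%, 55.1%, 26.8%, 30.4%, 68.3%, 22.2%, 19.6 points, 23.9 points and 16.6%. Summits within 200 bp gave 76.8%, 56.3%, 28.3%, 34.9%, 70.8%, 23.3%, 19.7 points, 25.7 points and 17.4%. Lists of equal length gave 33.3%, 32.1%, 16.8%, 19.2%, 62.2%, 18.4%, 19.5 points, 13.6 points and 3.68%. A ChIP height of at least 28 gave 82.5%, 58.9%, 30.5%, 37.0%, 81.0%, 22.5%, 12.2 points, 25.2 points and 18.6%. Regions beyond 1 kb of a 5′ end gave 85.5%, 66.7%, 27.8%, 32.5%, 71.4%, 19.7%, 21.4 points, 22.1 points and 17.4%. The upper 50% of each list gave 73.6%, 47.5%, 21.9%, 31.6%, 68.9% and 16.0% for the overlaps, 15.3 points for endoderm, with ESCs within the interval at 17.5 points, and 10.0% for the last. Standardized over tag enrichment the differences were 15.4 points in ESCs and 26.0 points in endoderm. Standardized over ChIP height the ESC difference was 1.84 points, so most of it went with the height of the co-bound regions, and standardized over promoter-proximal position the endoderm difference was 23.5 points. In the highest quintile of ChIP height the share kept with SB was 98.3% in ESCs and 34.7% in endoderm. The upper 50% of the lists held by construction 2055 (ESC SMAD2/3), 8611 (ESC HEB), 8384 (ESC+SB HEB), 5516 (Endoderm SMAD2/3), 9490 (Endoderm HEB) and 5073 (Endoderm+SB HEB) regions.

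Each alternative run on the gene list members used only a part of the assigned regions, so their numbers could stay or fall but not rise. At equal length the ESC HEB list held 8 Nodal/activin, 11 pluripotency, 6 definitive endoderm, 7 mesoderm, 12 neuroectoderm, 18 PRC2-bound, 4 PRC2/PRC1, 1 E protein or Id, 2 extraembryonic, 0 housekeeping and 2 receptor genes. The ESC+SB HEB list then held 9 Nodal/activin, 11 pluripotency, 2 PRC2/PRC1, 2 E protein or Id, 2 extraembryonic and 0 housekeeping genes. For Endoderm SMAD2/3 these were 1 mesoderm, 4 neuroectoderm, 1 PRC2-bound, 1 PRC2/PRC1, 1 E protein or Id, 4 extraembryonic and 1 housekeeping gene. Endoderm HEB held 8 Nodal/activin, 5 pluripotency, 9 definitive endoderm, 4 mesoderm, 4 neuroectoderm, 2 PRC2-bound, 3 PRC2/PRC1, 2 E protein or Id, 3 extraembryonic, 0 housekeeping and 1 receptor gene. Endoderm+SB HEB held 5 Nodal/activin, 10 neuroectoderm, 6 PRC2-bound, 3 PRC2/PRC1, 3 E protein or Id, 0 extraembryonic and 0 housekeeping genes.

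With the upper 50% of each list, ESC SMAD2/3 held 1 mesoderm, 1 neuroectoderm and 0 housekeeping genes, ESC HEB 3 extraembryonic, 0 housekeeping and 2 receptor genes, and ESC+SB HEB 3 E protein or Id, 4 extraembryonic and 1 housekeeping gene. Endoderm SMAD2/3 held 2 mesoderm, 4 neuroectoderm, 3 PRC2-bound, 2 PRC2/PRC1, 5 extraembryonic and 1 housekeeping gene. Endoderm HEB held 11 neuroectoderm, 12 PRC2-bound, 5 PRC2/PRC1, 2 E protein or Id, 6 extraembryonic and 0 housekeeping genes, and Endoderm+SB HEB 5 Nodal/activin, 10 neuroectoderm, 3 PRC2/PRC1, 3 E protein or Id, 0 extraembryonic and 0 housekeeping genes. Within 2 kb of a 5′ end, mesoderm genes numbered 0, 9, 8, 4, 9 and 1 in ESC SMAD2/3, ESC HEB, ESC+SB HEB, Endoderm SMAD2/3, Endoderm HEB and Endoderm+SB HEB. Neuroectoderm genes were then 0 in ESC SMAD2/3 and 4 in Endoderm SMAD2/3, extraembryonic genes 5 in Endoderm SMAD2/3 and 6 in Endoderm HEB, PRC2-bound regulators 6 in Endoderm+SB HEB, housekeeping genes 1 in ESC SMAD2/3, and receptor genes 0 in ESC HEB, ESC+SB HEB and Endoderm SMAD2/3 and 3 in Endoderm HEB. A ChIP height of at least 28 left 1 neuroectoderm and 1 housekeeping gene in ESC SMAD2/3, 4 extraembryonic genes in Endoderm SMAD2/3 and 3 housekeeping genes in Endoderm HEB. The other member counts were equal or lower by less than that margin.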

Other observations

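The test of list length below was planned before the data were seen. The test of open promoters was chosen after the data were seen but before its own value was, and the other tests and the gene families only after their results. The families partly hold genes of the lists described above. Hox genes, which pattern the body axis and stand in clusters, had a region at 37 of 39 in ESC HEB and in ESC+SB HEB, 1 in ESC SMAD2/3, 2 in Endoderm SMAD2/3, 11 in Endoderm HEB and 5 in Endoderm+SB HEB. Of the 26 on none of the lists, 26 had an ESC HEB region. In ESC HEB, 36 of the 39 had a region within 2 kb of their 5′ end, and the 37 came from 98 regions, none listed for more than 2 of them. Lhx genes, LIM homeobox factors, had HEB at 8 of 8 in ESCs with and without SB and at 7 in endoderm with and without SB, 4 of the 8 being on the lists. Fox genes, 6 of them on the lists, had HEB at 32 of 44 in ESCs (random lists, median 11 and highest 21) and 26 in endoderm.

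Protocadherin genes, cell adhesion genes that stand in clusters, shared regions, since 1 region in a cluster was listed for up to 21 of them in every list. The 22 of 69 with an ESC SMAD2/3 region came from 3 regions, the 38 in ESC HEB from 14 and the 39 in Endoderm+SB HEB from 11, so random lists of scattered genes give no chance level for these counts. Genes of ribosomal proteins, a family with strong promoters, had a region at 4 of 80 in ESC SMAD2/3 (median 6), 20 in ESC HEB (median 19), 35 in ESC+SB HEB (median 24), 17 in Endoderm SMAD2/3 (median 18), 25 in Endoderm HEB (median 20) and 29 in Endoderm+SB HEB (median 18). Single genes collected many regions. Msi2, which encodes an RNA-binding protein, had 28 in ESC HEB, and Auts2, a neurodevelopmental gene, had 17 in Endoderm SMAD2/3. In all HEB lists together, 2224 ESC HEB regions (12.9%) were shared, of which 44.0% were promoter-proximal. The region over Mir715 (chromosome 17, 39979863 to 39983418 in ESC SMAD2/3) was ranked first by the authors in 5 lists and had at least 1742 input tags in every list, so its tags are high without antibody.

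The large overlap of ESC SMAD2/3 with HEB (83.9%) was weighed against a pair of technical explanations. Noise of an input that both lists share may create common regions, yet 77.9% of ESC SMAD2/3 regions also overlapped the ESC+SB HEB list, called with another input, against 83.9% for the shared one. Unspecific pull-down of open promoters would make the overlap fall away from them, yet over regions beyond 1 kb of a 5′ end it was 85.5%. Both values argue against these explanations as the whole cause. Unspecific pull-down of open enhancers was not tested and stays open beside joint binding of both factors, which remains a hypothesis.

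The assignment of HEB regions to 31 and of SMAD2/3 regions to 0 of 35 PRC2-bound regulators in ESCs, with 1 HEB region (Hoxa13) over an unassigned SMAD2/3 region, was weighed likewise. The SMAD2/3 list is shorter, but with the ESC HEB list limited to the same 4111 regions 18 regulators still had HEB (51.4%, 95% CI 34.0 to 68.6), above the upper limit of 10.0% for SMAD2/3. A listing of CpG-rich promoters in general would give housekeeping and ribosomal protein genes HEB as often, yet 4 of 14 (28.6%, 8.39 to 58.1) and 20 of 80 (25.0%, 16.0 to 35.9) had an ESC HEB region, below the interval of the regulators (88.6%, 73.3 to 96.8). In ESC+SB HEB the ribosomal protein genes (43.8%, 32.7 to 55.3) again lay below the regulators (94.3%, 80.8 to 99.3), but the interval of the housekeeping genes, at 9 of 14 (64.3%, 35.1 to 87.2), reached theirs. These intervals take genes as independent. Yet 13 of the regulators are Hox genes, which stand in clusters and can share regions, so the intervals may be too narrow. CpG content and Polycomb occupancy were not measured here, so broad unmethylated CpG islands may still account for the regions, and binding of HEB at Polycomb targets remains a hypothesis.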
